A study of Homo sapiens with 2 samples.

How the data were processed

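RNA was measured on 2 Affymetrix arrays, 1 from KYSE170-luc cells transfected with an empty vector and 1 from the same line transfected with a SOX17 expression plasmid, both 12 h after transfection, per the labels. KYSE170-luc is a human esophageal squamous carcinoma line, and its suffix stands for luciferase, per the series title. Total RNA was extracted with Trizol and turned into biotinylated cRNA for hybridisation, per the labels' protocols. The deposited table holds 1 linear intensity per probe set and array, made by the authors with GCOS, per the submitters' processing notes. The algorithm, its settings, the GCOS version and the detection calls were not given in the sources used here. Without the lowest and highest 2% of its values, each array had a mean intensity of 500.1, so, by the values, they had been scaled to a common mean before deposit. Their medians differed by a factor of 1.10, and the values were used as deposited.

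Each array held 54675 probe sets, of which 62 were controls and were left out of the gene counts. Of the other 54613 probe sets, 41091 were paired with 1 gene by GEO's annotation of the platform, 1801 with several genes and 11721 with none. Only probe sets with 1 gene were named. Symbols were checked against a table of current RefSeq genes, and 0 needed an update. No genome build belongs to these values, so no coordinates are given.

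The floor was the 60th percentile of all values of both arrays pooled, an intensity of 95. A gene was represented by its probe set with the highest mean log2 value, and counted as measured when that probe set lay at or above the floor on both arrays. The log2 ratio is that of the SOX17 array over the empty vector array, so a positive value means a higher intensity on the SOX17 array. With 1 array per group there are no replicates, no p-value was computed, and the number of arrays limits the precision of every value. Genes were counted by size alone, at 2-fold. Where a gene lay at or above the floor on 1 array only, and there at 2 times the floor or more, its fold is the brighter intensity over the floor and is a lower bound. Measurement error was estimated from pairs of probe sets of the same gene. The SD of the difference of their log2 ratios, divided by the square root of 2, gave the SD of 1 ratio. It holds error within these arrays and leaves out the spread between cultures.

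The median log2 ratio of each of 23 gene lists was set against 10000 random lists of the same size. Random lists were drawn with replacement from measured genes within 20 bins of mean level (seed 1). A list was said to stand apart when its median lay in the outermost 2.5% of the random medians on either side, and lists with fewer than 5 measured members got no percentile. The percentile describes these 2 arrays and is no test of the conditions, since genes controlled together move together. Of 612 distinct listed genes, 65 had no probe set named to 1 gene and were not analysed here.

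The genes named in the text are SOX17, the 12 genes with the highest and the 12 with the lowest log2 ratio, up to 4 measured members of each list with the largest absolute log2 ratio, and for each array the 5 genes with the largest bound among those at 2 times the floor or more there and below the floor on the other array. The extreme genes and those with a bound had to have the same sign on every measured probe set, and uncharacterised loci and antisense genes were left out. Of the extreme genes only ARSK and TGS1 had more than 1 measured probe set, and the named genes with a bound had none. For all but ARSK and TGS1 the sign rule could not fail, and the values rest on 1 probe set each. Any other gene is named as chosen after its values were seen. The groups, lists, floor, threshold, rule for named genes and most alternatives were fixed before the data were examined. The alternatives were centring on the median ratio, quantile normalization, loess of the ratio on the level (span 0.4), floors at the 50th and 75th percentile or none, the mean over probe sets of a gene, leaving out probe sets whose ID ends in _x_at or _s_at, thresholds of 1.5-fold and 3-fold, and random lists from 10 bins or without matching. Random lists matched on level and gene length (10 bins of level with 5 of length each), and lists without genes that stand on several lists, were added after the data had been seen.

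The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6. They were tested on simulated data for the SOX17 against empty vector comparison, with the measured ratios shuffled among probe sets of like level as noise. By that construction the share of unchanged genes past 2-fold (0.784%) is close to the measured share, and it is no estimate of false calls. Of genes simulated 3-fold higher, 89.1% of the 46 measured passed 2-fold, and of those simulated 3-fold lower 97.8% of 46 did. At a simulated 1.5-fold, 8% of 50 measured genes simulated higher and 6.25% of 48 simulated lower passed 2-fold. Of 100 lists without a simulated shift, 3 fell in the outermost 2.5% of either side, and a list of 25 genes shifted by 0.3 on the log2 scale lay at percentile 100. These lists were drawn at random from genes with shuffled ratios. They do not show how often a list of genes that move together would stand apart.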

Results

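The data comprised 2 expression arrays from the esophageal squamous carcinoma line KYSE170-luc, 1 after transfection with an empty vector and 1 after transfection with SOX17, a transcription factor of the SOX family known for its part in endoderm and endothelial development. The comparison asks which transcripts differ 12 h after SOX17 is introduced into these cells. There was 1 array per group and no replicate, so each difference below is between these 2 arrays. Intensities ran from 0.1 to 64086.3 on the empty vector array and from 0.1 to 69631.3 on the SOX17 array. On the former 39.6% of probe sets lay at or above the floor of 95, and on the latter 40.3%. Of 19775 genes, 10034 were measured on both arrays. The log2 values of measured probe sets correlated with Pearson's r = 0.986 across probe sets, which are not independent replicates. The poly-A control transcripts, which are added to RNA before labelling, were higher on the SOX17 array on 24 of 24 probe sets, with a median log2 ratio of 0.57. The hybridisation controls, added after labelling, had a median of 0.11. The ratio of 3′ to 5′ signal was 11.6 on the empty vector array and 10.4 on the SOX17 array for ACTB, and 1.16 and 1.18 for GAPDH.

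SOX17 itself lay below the floor on both arrays. One of its probe sets read 4.5 on the empty vector array and 83.8 on the SOX17 array. The other read 19.1 and 6.5. Of the 5643 probe sets at or below 4.5 on the empty vector array, 32 (0.567%) reached 83.8 or more on the SOX17 array. No fold is given, because all 4 values were under the floor of 95. Whether either probe set lies in the sequence carried by the plasmid was not given in the sources used here, so these values leave the labels unchecked.

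Few genes differed by 2-fold between the SOX17 and the empty vector array. At that size 42 genes were higher and 33 lower on the SOX17 array, together 0.747% of the measured genes. Without replicates it is not known how many of them measurement error alone would give. The highest ratio among the genes named by rule was that of the histone gene H2AC14, at 127.1 on the empty vector array and 479.6 on the SOX17 array (3.77-fold). It rests on 1 measured probe set, whose ID ends in _x_at. TRIM22, an interferon-inducible antiviral gene, followed at 169.4 and 505.5 (2.98-fold), and its relative TRIM69 was 2.36-fold higher, from 767.3 to 1808.6. The other 9 of the highest were SERINC2 (2.85-fold), the ubiquitin ligase RNF167 (2.65-fold), CUTALP, PROSER3, the sulfatase ARSK, SLC66A3, the cochaperone gene DNAJC18, the adhesion receptor ADGRV1 and the zinc finger gene ZKSCAN2, the last 7 with log2 ratios of 1.18 to 1.33. ARSK had a log2 ratio of 1.25, but 0.40 on its other probe set, and its mean over probe sets (0.83) did not pass 2-fold. The lowest ratio was that of SPATC1, which read 331.3 on the empty vector array and 102.5 on the SOX17 array (log2 ratio -1.69). HCFC1, a transcriptional coregulator, had a log2 ratio of -1.44, and the zinc finger gene ZNF215 of -1.38. TGS1, which makes the trimethylguanosine cap of small nuclear RNAs, read 2614.7 and 1042.5 (-1.33), but its other probe set had a log2 ratio of -0.05, and the mean over both (-0.69) did not pass 2-fold. NCKIPSD, MIER2, HUS1B, CCDC157, the pseudogene SUZ12P1, the SUMO protease SENP7, TMA16 and the matrix protein gene PRELP lay between -1.30 and -1.18.

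**Figure D1:**
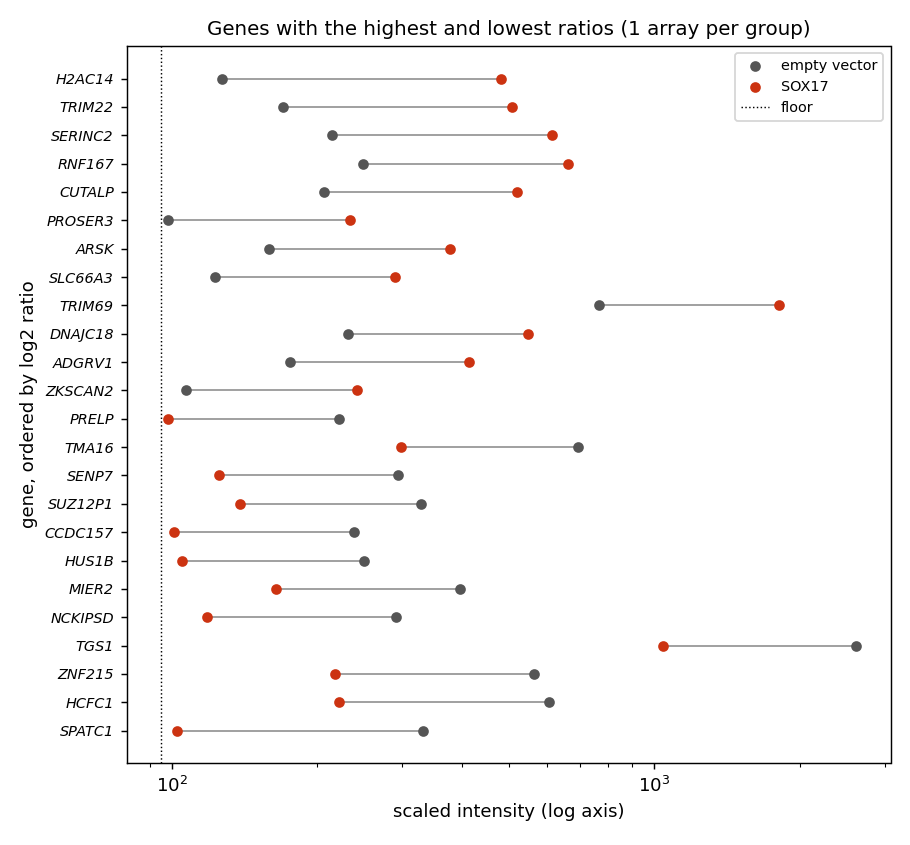
Scaled intensity (log axis) of the 12 genes with the highest and the 12 with the lowest log2 ratio of the SOX17 array (red) over the empty vector array (grey), 1 array per group, with a line joining the values of a gene and a dotted line at the floor of 95. Among these 24 genes TRIM69 and TGS1 have the highest intensities, and no other gene exceeds 693.1.

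A further 32 genes were below the floor on the empty vector array and at least 2 times the floor on the SOX17 array, and 20 genes the reverse. In the first group TTC38 was at least 2.65-fold higher, the thiamine triphosphatase THTPA at least 2.54-fold, CAPN15 at least 2.53-fold, the acyl-CoA thioesterase ACOT11 at least 2.49-fold and the proton pump subunit ATP6V0D2 at least 2.40-fold. In the second, the creatine synthesis enzyme GAMT was at least 3.43-fold higher on the empty vector array, the mTORC1 subunit RPTOR at least 3.16-fold, ARHGAP24 at least 2.54-fold, B4GALT6 at least 2.53-fold and pyruvate carboxylase (PC) at least 2.37-fold.

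The probe sets of a gene gave a measure of error for these ratios. Over 4574 genes with several measured probe sets, the SD of 1 log2 ratio was 0.27. It was 0.36 in the lowest tertile of level, 0.26 in the middle and 0.18 in the highest. Ratios from different probe sets of a gene correlated with Pearson's r = 0.264 and Spearman's rho = 0.290 across genes, which are not independent replicates. Of the 75 genes past 2-fold, 58 came from the lowest tertile of level of all measured genes. Of the 18 with several measured probe sets, 10 had probe sets of opposite sign. MAP2K5, chosen here after its values were seen, had the largest ratio of all (7.01-fold higher), yet its 4 probe sets ranged from -0.31 to 2.81 on the log2 scale. No gene with several measured probe sets passed 2-fold on every one.

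At 1.5-fold, 9 genes were higher and 14 lower on every probe set. Shuffling the ratios gave on average 4.19 and 8.49 such genes, and at most 11 and 17 in 1000 shuffles. Both numbers thus lay above the mean of the shuffles and below their highest. Their rank among the shuffles was not computed, so how often shuffling gives as many is not known here. The genes were chosen after their values were seen. Higher on the SOX17 array were the chemokine CCL5 (log2 ratios of 0.68 to 0.75), the double-stranded RNA receptor TLR3 (0.76 to 0.89), the interferon-inducible helicase HELZ2 (0.86 to 1.10), the cornified envelope gene SPRR1A (0.64 to 0.67), the homeobox gene MEIS1, the translesion polymerase POLH, KICS2, TTLL11 and TUBGCP2. Lower were the prostaglandin synthase PTGS2, at 22876.3 on the empty vector array and 11692.3 on the SOX17 array (-1.34 to -0.97), the protease ADAMTS1 (-0.99 to -0.81), the stress phosphatase subunit PPP1R15A (-0.75 to -0.67), the cytokine receptor LIFR (-0.75 to -0.60), the transcription cofactor VGLL3 (-0.69 to -0.64), ATXN1, ATXN7, CCNT2, DENND4A, KCTD12, PLCE1, SPOPL, UGGT2 and ZDHHC21.

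Genes of the type I interferon response were higher on the SOX17 array than on the empty vector array. Of 28 measured members 21 had a ratio above 0, 5 were at least 1.5-fold higher and 1 was at least 1.5-fold lower. IFI27 read 362.1 and 773.2 (log2 ratio 1.09) and was the 1 member past 2-fold. USP18, which removes ISG15 from proteins, had a log2 ratio of 0.75, and the antiviral gene IFI6 of 0.72. The interferon gene IFNL1 went the other way, from 187.6 on the empty vector array to 114.5 on the SOX17 array (-0.71). The list's median was 0.28 (1.21-fold), and none of the 10000 random lists had as high a median (0 of 10000). Among members chosen after their values were seen, ISG15 read 36170.9 on the empty vector array and 43066.6 on the SOX17 array, and IFIT1 read 31422.5 and 30554.2. The poly-A controls, with their median of 0.57, were higher on the same array. Of 17 leukocyte genes with a named probe set 1 was measured, the B cell receptor gene CD79A, with a log2 ratio of -0.21.

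Immediate early genes, which respond first to growth factors and stress, were lower on the SOX17 array. Of 23 measured members 21 had a ratio below 0, 3 were at least 1.5-fold lower and 0 at least 1.5-fold higher. The phosphatase DUSP2 had a log2 ratio of -0.78, the matricellular gene CCN1 of -0.71 (15944.2 and 9766.5), the AP-1 subunit JUNB of -0.67 and JUN of -0.53 (8154 and 5651.6). The 4 measured probe sets of JUN ranged from -1.05 to -0.44, and the 2 of CCN1 from -0.71 to -0.33. The list's median was -0.35 (1.27-fold lower), and 0 of 10000 random lists had as low a median.

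Targets of the tumour suppressor p53 and genes of protein and stress responses also had lower medians on the SOX17 array. Of 19 measured p53 targets 14 had a ratio below 0, with a median of -0.24 (1.18-fold lower, as low in 9 of 10000 random lists). The cell cycle inhibitor CDKN1A had a log2 ratio of -0.74, the p53 ubiquitin ligase MDM2 of -0.53, the pro-apoptotic gene PMAIP1 of -0.50 and SESN1 of 0.51. MDM2 had 4 measured probe sets, which ranged from -0.62 to 0.41. Of 28 genes of the unfolded protein and integrated stress response 20 had a ratio below 0 (median -0.15, percentile 0.15). DDIT4, an inhibitor of mTORC1, had a log2 ratio of -0.89, CHAC1, which breaks down glutathione, of -0.88, PPP1R15A of -0.75 and the transcription factor ATF3, which stands on the immediate early list too, of -0.51. Of 14 heat shock protein genes 9 had a ratio below 0 (median -0.16, percentile 0.33), among them HSPA6 (-0.62), HSPA4L (-0.45), HSPH1 (-0.37) and CHORDC1 (-0.36). The other probe set of CHORDC1 had a log2 ratio of 0.18, and the 3 of HSPH1 ranged from -0.38 to -0.04. Without probe sets ending in _x_at or _s_at the p53 list lay at percentile 5.38 and the heat shock list at 26.2, and neither then stood apart. Of the 20 lists with a percentile 1 stood apart higher and 4 lower, against 1 expected by chance if lists were independent.

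**Figure D2:**
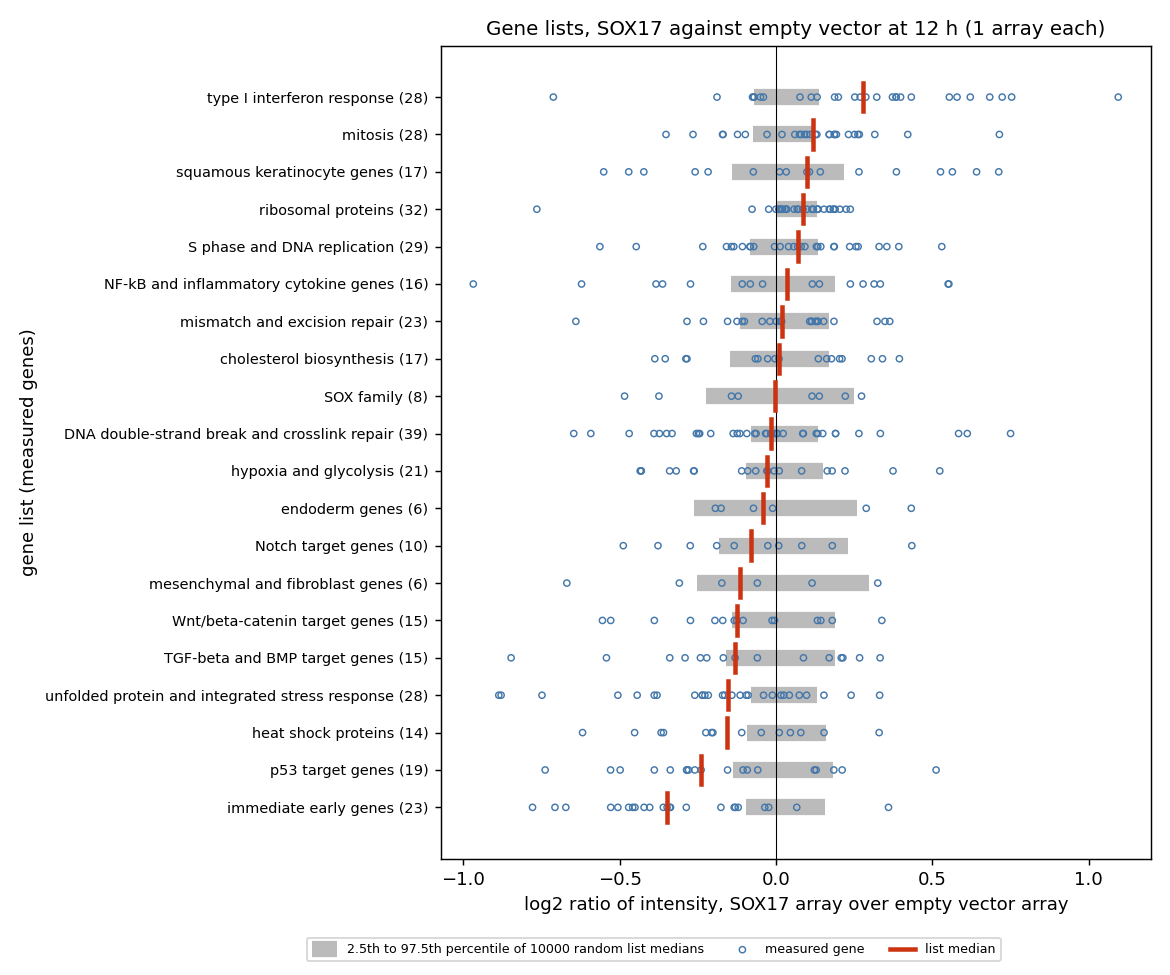
Log2 ratio of intensity, SOX17 array over empty vector array, for the 20 gene lists with at least 5 measured genes (number in parentheses), with open circles for genes, red bars for list medians and grey bands for the medians of 10000 random lists matched on level without the outermost 2.5% on each side. The median of the interferon list (0.28) lies above its band, and those of the immediate early (-0.35), p53 target (-0.24), heat shock (-0.16) and unfolded protein response (-0.15) lists lie below theirs.

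**Figure D3:**
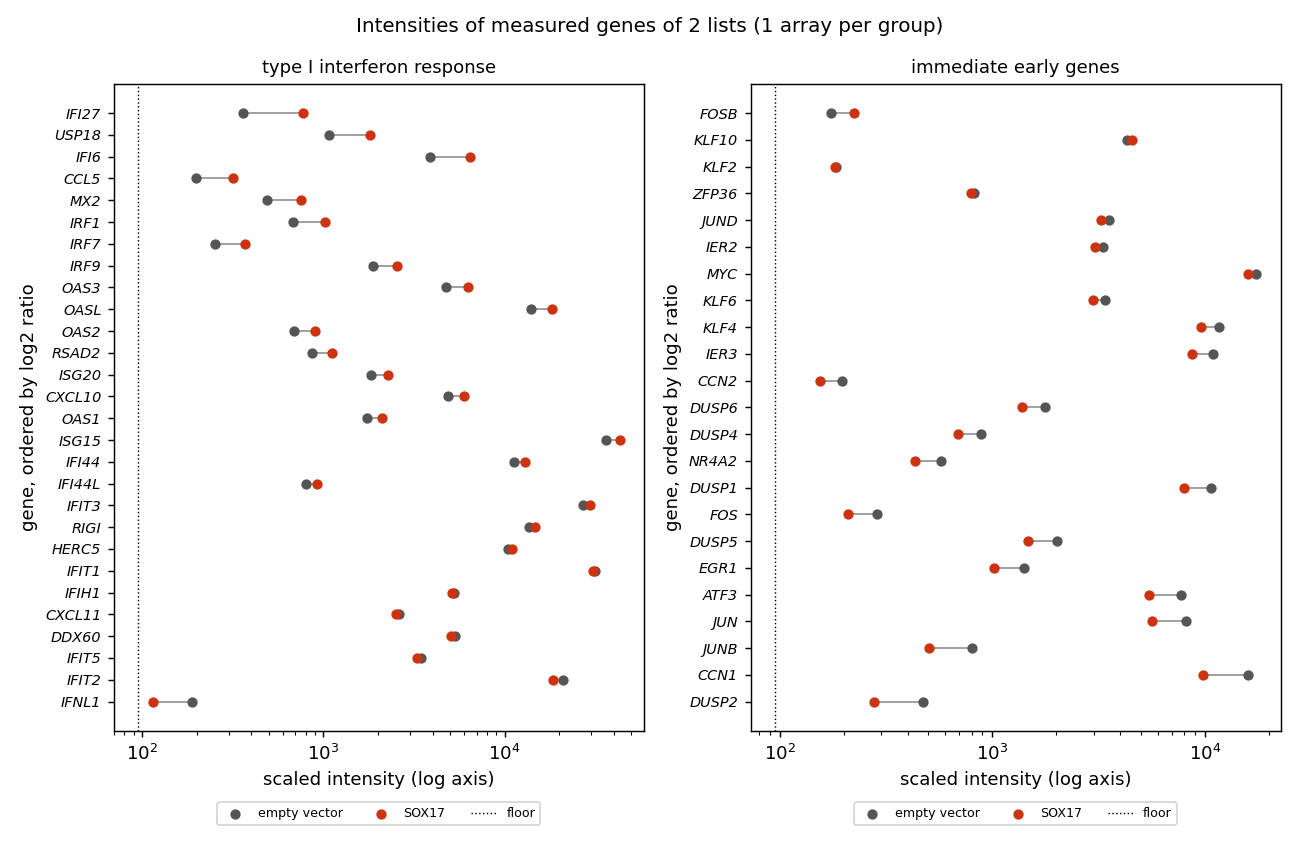
Scaled intensity (log axis) of each measured gene of the type I interferon list (left) and the immediate early list (right) on the empty vector array (grey) and the SOX17 array (red), 1 array per group, ordered by log2 ratio, with a dotted line at the floor of 95. The ratio was above 0 for 21 of 28 interferon genes and below 0 for 21 of 23 immediate early genes.

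Among signalling pathways, Wnt/beta-catenin targets had a median log2 ratio of -0.13 (15 measured, 11 below 0, percentile 3.40). EPHB3 lay at -0.56, TCF7L2, a transcription factor of the pathway, at -0.39 and the protease MMP7 at 0.34, and JUN stands on this list too. TCF7L2 had 5 measured probe sets, which ranged from -0.39 to 0.36. TGF-beta and BMP targets had a median of -0.13 (15 measured, 9 below 0, percentile 4.19), with ID2 at -0.85, SMAD6 at -0.54, CCN2 at -0.34 and TGIF1 at 0.33 (3 probe sets, -0.14 to 0.33). Among random lists matched on gene length as well as level, chosen after the data were seen, both lists stood apart (Wnt at percentile 2.06 and TGF-beta at 1.47). The sign of the TGF-beta median turned with a floor at the 75th percentile (0.09) and with no floor (0.01). With no floor the Wnt median was -0.005 (percentile 23.9), and without genes on several lists the Wnt list lay at percentile 7.39. Notch genes had a median of -0.08 (10 measured, percentile 14.6), with NOTCH1 at -0.49, HES2 at 0.43, NRARP at -0.38 and NOTCH3 at -0.27. Of 16 NF-kB and inflammatory genes 8 were above 0 and 8 below (percentile 51.0). PTGS2 lay at -0.97 and LIF at -0.62, while the chemokines CXCL1 and CXCL8 both lay at 0.55.

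No lineage list that had a percentile stood apart. The medians rest on genes at or above the floor on both arrays. A lineage gene below the floor on 1 array could not move them, so they cannot show whether such a gene was switched on. Of 18 SOX family genes with a named probe set 8 were measured, 4 above 0 and 4 below (percentile 40.5). SOX9 lay at -0.48, SOX12 at -0.37, SOX2 at 0.27 and SOX15 at 0.22. The other probe set of SOX9 lay at -0.12, that of SOX2 at 0.09 and that of SOX15 at 0.55. Of 21 endoderm genes with a named probe set 6 were measured, and 4 of these lay below 0 (median -0.04, percentile 33.8). HHEX lay at 0.43, FOXA1 at 0.29, GATA6 at -0.19 and LAMB1 at -0.18 (0.06 on its other probe set). Of 23 endothelial genes with a named probe set 4 were measured: the VEGF receptor FLT1 (-0.92), ERG (-0.33), EGFL7 (0.15) and EFNB2 (0.15). Squamous keratinocyte genes had a median of 0.10 (17 measured, percentile 68.0), with SPRR3 at 0.71, SPRR1A at 0.64, KRT16 at 0.56 and the transcription factor GRHL3 at -0.55. Of 22 mesenchymal genes with a named probe set 6 were measured, and 4 of these lay below 0 (median -0.12, percentile 14). S100A4 lay at -0.67, FN1 at 0.33 (4 probe sets, -0.05 to 0.62), TWIST1 at -0.31 and CDH2 at -0.17. Of 37 genes of unrelated tissues with a named probe set 2 were measured, the olfactory receptor OR2C1 (0.68) and the myelin gene MBP (-0.01, with 3 probe sets from -0.02 to 0.08). OR2C1 read 96.5 on the empty vector array and 154.3 on the SOX17 array, near the floor.

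Proliferation and repair lists lay inside the range of random lists. Mitosis genes had a median of 0.12 (28 measured, 21 above 0, percentile 96.2), with the kinesins CENPE at 0.71 and KIF20A at 0.42, the checkpoint kinase TTK at -0.35 and securin (PTTG1) at 0.32. After quantile normalization this list lay at percentile 98.4 and after loess at 98.9, in the outermost 2.5%. With the mean over probe sets it lay at percentile 84.2. Among random lists not matched on level it lay at 91.3, and at 92.5 after loess. S phase genes had a median of 0.07 (29 measured, percentile 75.5), with MCM2 at -0.56, RFC2 at 0.53 (0.06 on its other probe set), POLE at -0.45 and RFC4 at 0.39. Double-strand break and crosslink repair genes had a median of -0.02 (39 measured, percentile 17.4), with XRCC2 at 0.75, FANCB at -0.65, FANCF at 0.61 and SIRT1 at -0.59. Mismatch and excision repair genes had a median of 0.02 (23 measured, percentile 41.3), with LIG1 at -0.64, DDB1 at 0.36, ERCC3 at 0.35 and ERCC1 at 0.32 (3 probe sets, -0.02 to 0.33).

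The lists fixed for metabolic and ribosomal genes did not stand apart either. Hypoxia and glycolysis genes had a median of -0.03 (21 measured, percentile 14.7), with the glucose transporter SLC2A1 at 0.52, hexokinase HK2 at -0.43, NDRG1 at -0.43 and VEGFA at -0.43. Cholesterol biosynthesis genes lay 9 above 0 and 8 below (17 measured, percentile 43.5), with SREBF2 at 0.39, INSIG1 at -0.39, MVK at -0.35 and EBP at 0.34. The other probe set of SREBF2 lay at 0.10, and the 3 of INSIG1 ranged from -0.39 to -0.03. Of 32 ribosomal protein genes 28 lay above 0 (median 0.09, percentile 66.8), but the sign of the median turned after quantile normalization (-0.02) and loess (-0.01). RPLP2 lay at -0.77, on 1 measured probe set. It read 200.2 on the empty vector array and 117.8 on the SOX17 array, near the floor. Far brighter on both arrays were RPS23 at 0.24 (54343 and 64064), RPS15 at 0.22 (38780 and 45298.6) and RPL38 at 0.20 (38391.2 and 44225.1). Whether the RPLP2 probe set reports the level of its transcript was not tested. RPL38 had 3 probe sets, which ranged from -0.81 to 0.20, and their mean was -0.34.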

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

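The ratios of the control probe sets were planned as a measure of error. The probe sets not paired with 1 gene were looked at only after the arrays had been seen. No cause was tested for either. The 24 probe sets of the poly-A control transcripts, which belong to no gene of the cells, had a median log2 ratio of 0.57 between the SOX17 and the empty vector array (1.49-fold), with a range of 0.23 to 1.02. Whether both labelling reactions held the same proportion of control to sample RNA stays open. Every gene ratio is relative to the common mean of the arrays, so a change of all transcripts alike would not show in it. Among 2700 measured probe sets that were not paired with any 1 gene, 12 were at least 2-fold higher on the SOX17 array and 33 at least 2-fold lower.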

How the results depend on the processing

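The random lists matched on gene length and the lists without genes on several lists were chosen only after the results had been seen, and the other settings were planned. The counts of genes depended most on the floor. With a floor at the 50th percentile 125 genes were at least 2-fold higher and 82 lower, and 130 and 49 were at least 2 times the floor on the SOX17 or empty vector array and below the floor on the other. At the 75th percentile these were 7 and 9, and 3 and 1. With no floor they were 2811 and 1874, with 221 higher and 98 lower on every probe set. The lower values are at or near background, where the arrays have least precision. A 1.5-fold threshold gave 379 higher and 320 lower, with 9 and 14 on every probe set, and a 3-fold threshold 2 and 1. After quantile normalization and after loess, 1 gene, PTGS2, was 2-fold lower on every probe set. The mitosis list stood apart after quantile normalization (0.12, percentile 98.4) and loess (0.12, percentile 98.9). The heat shock list no longer stood apart with the mean over probe sets (-0.091, percentile 3.36), without _x_at and _s_at probe sets (-0.045, 26.2) and without matching (-0.16, 2.69), nor did the p53 list without _x_at and _s_at probe sets (-0.20, 5.38). With length matching the TGF-beta (-0.13, 1.47) and Wnt lists (-0.13, 2.06) stood apart. The cause of these shifts in lists was not tested. The interferon (0.26 to 0.30), immediate early (-0.46 to -0.34) and unfolded protein response medians (-0.18 to -0.11) stayed on their side of the limit in all 12 settings run for them. Of the lists that stood apart before any setting was changed and the genes named by rule as highest or lowest, none changed direction in the settings run for them. The TGF-beta list, which stood apart only with length matching, turned sign with a floor at the 75th percentile (0.09) and with no floor (0.01). Genes named only after their values were seen and genes below the floor on 1 array were not run singly. The DUSP family changed direction with no floor, and at the 75th percentile floor more genes were lower than higher. With the mean over probe sets, the log2 ratios of ARSK (0.83) and TGS1 (-0.69) no longer passed 2-fold. Among genes under 2-fold, the ratios of RPL38 (-0.34, mean over probe sets), CHORDC1 (0.18) and TGIF1 (-0.14, both without _x_at and _s_at probe sets) changed sign, as did that of MBP near 0, and RFC2 lay at 0.06 without _x_at and _s_at probe sets. No paired analysis was possible because the groups share a single replicate number, and no replicate could be left out with 1 array per group.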

Other observations

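The gene families in this part and the tests of scaling and of the dishes were chosen only after the results had been seen, while the tests of gene length were set out before their results were known. Genes that share the leading letters of their symbol were treated as families, and 153 had at least 8 measured members. Of these 11 lay in the lowest 2.5% of random lists and 10 in the highest 2.5%, against 3.83 expected on each side by chance. Some families of mitochondrial genes were higher on the SOX17 array, and others lay inside the range of random lists, among them NDUFB (percentile 93.8), NDUFAF (82.9), COX (94.4) and ATP (95.2), the last with members outside mitochondria. The NDUFA subunits of complex I had a median log2 ratio of 0.24 (10 of 12 above 0), with NDUFA7 at 0.51 and NDUFA1 at 0.43 but NDUFA10 at -0.34. The COQ genes of coenzyme Q synthesis had a median of 0.33 (9 of 11 above 0), with COQ9 at 0.51 and COQ5 at 0.48 but COQ10B at -0.28. The PSMB genes of the proteasome had a median of 0.25 (9 of 10 above 0). The largest PSMB ratios were those of the interferon-inducible subunits PSMB8 (745.3 and 1248.8, 0.74), PSMB9 (629.1 and 1047.7, 0.74) and PSMB10 (0.39). Over 8 other settings the medians stayed at 0.20 to 0.28 for NDUFA, 0.25 to 0.35 for COQ and 0.19 to 0.25 for PSMB. The RPL family of cytosolic ribosomal genes (39 measured, median 0.13, percentile 98.0) lay at percentile 90.5 after loess and 87.8 after quantile normalization, and at 78.9 among random lists matched on gene length too.

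The families on the lower side included USP (percentile 0.74), RAD (0.90), ZBTB (0.94) and PRPF (1), which are not described further. Also on that side stood the GALNT genes, which start mucin-type O-glycosylation, with a median of -0.29 (9 of 10 below 0). Among the GALNT genes were GALNT14 (-0.39), GALNT3 (-0.30) and GALNT6 (-0.50, with its other probe set at 0.34). Their percentile was 0.47, and ranged from 0.26 to 5.70 over 8 other settings. The dual specificity phosphatases (DUSP), of which several stand on the immediate early list, had a median of -0.30 (10 of 16 below 0). The sign of the DUSP median turned with no floor (0.07). Across 10023 measured genes with a known length, the log2 ratio fell with gene length (Spearman's rho = -0.187, across genes, which are not independent replicates). The median was 0.11 in the quintile of shortest genes and -0.05 in that of the longest.

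The interferon genes were higher on the SOX17 array, with a median log2 ratio of 0.28. Gene length bias is argued against as the whole cause, because the list lay at percentile 100 among random lists matched on level and length. Level-dependent scaling is too, since the median was 0.28 after loess, at percentile 100 among random lists not matched on level. A response to SOX17 and a difference between the 2 dishes other than SOX17, such as the amount of plasmid or the condition of the cells, cannot be told apart with 1 array per group. Either may account for the shift. The SOX17 probe sets do not help to decide, since 1 read 4.5 on the empty vector array and 83.8 on the SOX17 array, the other 19.1 and 6.5, all below the floor.

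The immediate early genes were lower on the SOX17 array, with a median of -0.35. Short genes tended to be higher, and random lists matched on level and length had a median of 0.10, against 0.04 for those matched on level alone. Length would thus raise this list, which argues against gene length bias as a cause of its lower ratios. The list lay at percentile 0 among both kinds of random list. Since length acts in the other direction, matching on it could hardly have moved the list inside the range. After loess its median was -0.35, at percentile 0 among random lists not matched on level, which argues against level-dependent scaling as the whole cause. These genes respond within minutes to handling, serum and stress, so a difference between the 2 dishes other than SOX17 may have moved them, and with 1 array per group this cannot be told apart from a response to SOX17.

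The genes of the mitochondrial ribosome were higher on the SOX17 array, with 67 of 75 above 0 and a median log2 ratio of 0.16. This list joins the MRPL and MRPS families, which lay at percentiles 99.95 and 99.97 in the scan of families in these same data. Its high percentiles are thus no independent evidence of a shift. Random lists matched on level and length had a median of 0.07, against 0.02 for those matched on level alone, so length may account for part of the shift. The list lay at percentile 99.98 among the former. With 5 bins of length the match is coarse, so it cannot set an upper limit to the part of length. After loess the median was 0.15, at percentile 99.9 among random lists not matched on level, which argues against level-dependent scaling as the whole cause. Without _x_at and _s_at probe sets 38 genes were left, with a median of 0.10 at percentile 97.7. A response to SOX17 and a difference between the 2 dishes other than SOX17 may each be the source, and with 1 array per group they cannot be told apart.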
